A study of Homo sapiens with 48 samples.

How the data were processed

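Gene expression had been measured on Affymetrix U133 Plus 2.0 arrays in the human bronchial epithelial cell line BEAS-2B, 1 array per sample. Per the labels, confluent cells received vehicle, indacaterol with GSK256066 (Ind/GSK, both at 10 nM) or GS-5759 (10 nM) for 1, 2, 6 or 18 h, with 4 replicates each. That gave 12 groups and 48 arrays. Replicate numbers came from the sample titles. Per the labels' protocols, cells had been cultured in keratinocyte serum-free medium with growth supplements and then 24 h without them, RNA had been isolated with RNeasy, and biotin-labelled cRNA had been made by 3' in vitro transcription. The labels do not state that the replicates were separate cultures, so the p-values measure the spread between these samples.

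The deposited values were probe set intensities on a linear scale, made by the authors with PLIER in Affymetrix Expression Console, per the submitters' processing notes. Versions of both and the normalization between arrays were not stated. No value was 0. After log2(value + 16) the array medians ran from 6.999 to 7.173, within the tolerance of 0.2 set beforehand, so the arrays were used as deposited. Correlations between arrays ran from 0.9684 to 0.9966, and no 2 columns were identical.

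Of 54675 probe sets, 62 were controls, 11721 had no gene symbol, 41091 had 1 and 1801 had several. Symbols of 41037 were matched to current ones through their gene identifiers. The brightest probe set with exactly 1 symbol stood for each of 19775 genes. Genes whose mean lay above the 40th percentile (log2 6.514, a signal of 75.42) were tested, 14409 in number. Genes below that signal were not tested. The 4 probe sets of PDE4C are shared with other symbols.

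Group means were fitted over all 48 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 36 residual degrees of freedom, prior 2.371), because all groups then share 1 estimate of spread. Contrasts compared each treatment with vehicle at the same time, GS-5759 with Ind/GSK at each time and over all 4 times, the mean response of both treatments between neighbouring times, and vehicle at 18 h with vehicle at 1 h. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. A 2-fold size was reported beside the calls. Data were read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

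Genes named in the text followed a rule set before the data were examined. For each comparison with vehicle these were the 10 largest rises and 5 largest falls among called genes in which all 4 treated arrays lay beyond all 4 vehicle arrays. For the average difference between treatments, the responses over time and vehicle over time, the 5 largest in each direction were named. From each fixed list up to 4 called members were added, and PDE4 genes were always given. Only probe sets with exactly 1 symbol were named.

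Fixed gene lists, 26 in number, were written from general knowledge before the data were examined: cAMP-CREB target genes; cAMP breakdown and β2-receptor regulation; anti-inflammatory and bronchoprotective effector genes; glucocorticoid-inducible genes; inflammatory cytokines, chemokines and adhesion molecules. Further response lists held interferon-stimulated genes, immediate early genes, MAP kinase feedback inhibitors, YAP and SRF target genes, extracellular matrix and TGF-beta response genes, G1/S and DNA replication genes, G2/M and mitosis genes, and cell cycle inhibitors. Others held cholesterol synthesis, unfolded protein and integrated stress response, NRF2 target and clock genes, EGF receptor ligands and receptors, and airway ion transport and mucin genes. Cell type lists held airway basal and squamous, ciliated and club cell, fibroblast, leukocyte and endothelial markers, and quality lists heat shock and reference genes. Lists with at least 5 tested genes were compared with all other genes by camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were also adjusted over the list alone. Fry was run on each list as well, but its p-values rest on 4 arrays per group with no exact test behind them and are not printed.

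The responses to both treatments were compared by correlation over all genes. Because they share vehicle arrays, unchanged genes were simulated with 100 draws for the correlation and 20 for shared calls, which called none and so decide nothing, and vehicle arrays were split between the treatments in 6 assignments. Intervals of the difference between treatments were at 95%.

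Same-numbered samples were checked for pairing: over genes, all 52 pairs of same-numbered arrays correlated above the minimum of 0.1 after group means were removed (0.2 to 0.93). Arrays of different numbers also reached correlations of up to 0.75, above the lowest same-numbered pair in all comparisons but GS-5759 against vehicle at 18 h. By the minimum set, the numbers were taken to pair samples, and a fit with the replicate number as a block (1 term per number) is given beside counts of called genes, list members and genes shared by the treatments where it moves them by more than 1.5 times; overlaps between times and peak times were counted without it. Entered as a random effect, the replicate number had a consensus correlation of 0.436.

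Other choices tried were 75th percentile centring, quantile normalization, log2(value + 1), no filter, a 60th percentile filter, every probe set, another probe set of a named gene, limma with trend and robust, only the arrays of the groups named, the 2-fold size, and leaving out each array in turn. Fits without replicate 3 and fits joining a scaling with the block were added after the data had been seen. Chance was assessed by calling genes after every split of the 8 arrays of a comparison, 35 in number, or 100 drawn ones where more groups entered.

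The steps were tested on simulated data shaped like Ind/GSK against vehicle at 2 h, with 14409 genes and 50 changed genes for each of 1.5-, 2-, 4- and 8-fold. Without the block 64, 84, 98 and 100% of the changed genes were called, with 0 false among 173 calls. With the block 92, 98, 100 and 100% were called, with 8 false among 203 (3.94%). Values were drawn from the block fit itself, with independent normal noise and no offset of whole arrays. The false share therefore need not hold for the block counts in the real arrays. Precision is limited by the number of arrays, 4 per group. Probe sets with no symbol or several were tested apart and enter no comparison of the report.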

Results

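Gene expression was compared in BEAS-2B human bronchial epithelial cells given vehicle, indacaterol with GSK256066 (Ind/GSK), or GS-5759. Indacaterol is a long-acting β2-adrenoceptor agonist, GSK256066 a phosphodiesterase 4 (PDE4) inhibitor and GS-5759 a bifunctional molecule with both activities. Changes below are log2 differences between group means with their SE, n = 4 arrays per group. A gene, or its response between times, is called risen or fallen only where adjusted p passed 0.05. In leading genes all 4 treated arrays lay beyond all 4 vehicle arrays. The comparisons, gene lists and main model were chosen before the data were examined. Where no other number is given, a list's count was the same adjusted over the list alone. Leave-1-out tallies of genes cover those refitted, which are not all the genes named below.

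NR4A2, NR4A3 and IL6 led the response to Ind/GSK at 1 h. NR4A2 rose by 4.08 ± 0.73 (16.9-fold; mean signal 127 ± 41.8 SD with vehicle and 3940 ± 4410 SD with Ind/GSK) and NR4A3 by 3.60 ± 0.57, from a mean vehicle signal of 46.1, below the filter level of 75.42. Both encode nuclear receptors without a known ligand and are known CREB targets. IL6, a cytokine, rose by 3.25 ± 0.48 (9.54-fold), and CXCL2, a chemokine for neutrophils, by 2.06 ± 0.41 (4.17-fold, 0.11 for its other probe set). PRDM1, a transcriptional repressor, rose by 2.55 ± 0.26 (5.85-fold), and SIK1, a kinase that holds back CREB coactivators, by 2.23 ± 0.38 (4.70-fold). SGK1, a kinase known to be induced by glucocorticoids, rose by 2.12 ± 0.21 (4.33-fold), and RGS2, which limits Gq signalling, by 2.07 ± 0.28 (4.19-fold). TRIB1, a pseudokinase, rose by 2.06 ± 0.17 (4.16-fold) and EDN1, the precursor of endothelin-1, by 1.71 ± 0.17 (3.28-fold). The largest falls were those of MIR181A2HG (-0.77 ± 0.17), LOC401261 (-0.66 ± 0.18), the zinc finger gene ZNF57 (-0.61 ± 0.08), LOC105372255 (-0.60 ± 0.16) and SERTAD3 (-0.54 ± 0.09). Adjusted p ran from 2.49e-10 for TRIB1 to 0.0432 for LOC401261.

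Limma called 264 of 14409 genes with Ind/GSK at 1 h: 65 risen, 18 of them at least 2-fold, and 199 fallen, none at least 2-fold. At unadjusted p under 0.05 there were 2651. The direction split depended on array scaling: 196 risen and 15 fallen after centring on the 75th percentile, 83 risen and 20 fallen after quantile normalization. The same centring moved the median change of all genes from -0.097 to 0.024. The Ind/GSK arrays had a mean 75th percentile signal of 556.1, against 576.5 with vehicle and 583.8 with GS-5759. ZNF57 and SERTAD3 were called as fallen under both scalings, whereas LOC401261 and LOC105372255 were called under neither. With the replicate number as a block, 328 genes rose and 2280 fell. Leaving out 1 array gave 78 genes without Ind/GSK replicate 1, 90 without Ind/GSK replicate 2, 433 without Ind/GSK replicate 4, 75 without vehicle replicate 1 and 74 without vehicle replicate 2. Of 23 refitted genes, 19 were called in all 8 such fits; MIR181A2HG, LOC401261, LOC105372255 and POSTN were not.

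NR4A2, NR4A3 and IL6 also led the response to GS-5759 at 1 h. NR4A2 rose by 4.15 ± 0.73 (17.8-fold; mean signal 3550 ± 3030 SD), NR4A3 by 3.87 ± 0.57 and NR4A1, the remaining member of that receptor family, by 1.93 ± 0.33 (3.80-fold, with -0.03 and 1.70 for its 2 other probe sets). IL6 rose by 3.35 ± 0.48 (10.2-fold) and CXCL2 by 2.29 ± 0.41 (4.89-fold, 0.15 for its other probe set). PRDM1 rose by 2.73 ± 0.26 (6.62-fold), SIK1 by 2.36 ± 0.38 (5.12-fold), SGK1 by 2.19 ± 0.21 (4.57-fold), TRIB1 by 2.19 ± 0.17 (4.56-fold) and RGS2 by 2.12 ± 0.28 (4.34-fold). Only ZNF57 (-0.45 ± 0.08) and LOC286437 (-0.32 ± 0.07) fell. Adjusted p for NR4A2 was 0.001, for PRDM1 7.17e-09 and for LOC286437 0.0308. Limma called 39 genes: 37 risen, 19 of them at least 2-fold, and 2 fallen; 601 had an unadjusted p under 0.05. Quantile normalization gave 38 risen and 8 fallen, and the replicate block 144 risen and 51 fallen. No single array moved the count beyond the range 31 to 39. LOC286437 and SPRY2 were the only ones of 18 refitted genes not called in all 8 leave-1-out fits.

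Several fixed gene lists held risen members with both treatments at 1 h. Of 17 cAMP-CREB target genes, 8 rose with each treatment, among them NR4A1 (1.65 ± 0.33 with Ind/GSK, 0.08 and 1.59 for its other probe sets) and SIK1; the list medians were 0.70 and 0.83 (camera adjusted p = 1.39e-26 and 3.42e-44). Adjusted over the list alone, 10 and 11 rose, and 13 and 13 with the replicate block. Of 20 immediate early genes, 6 rose with each, among them KLF6 (0.75 and 0.78), MYC (0.72 and 0.86) and FOSL2 (0.52 and 0.59), transcription factor genes (list adjusted p = 1.97e-10 and 4.7e-18). Adjusted over the list alone, 6 and 8 rose and 1 fell with each; the block gave 11 and 10 risen, with 5 fallen for Ind/GSK. Of 18 anti-inflammatory and bronchoprotective effector genes, 4 rose with each, among them RGS2 and DUSP1 (0.70 and 0.70), a MAP kinase phosphatase (adjusted p = 1.99e-16 and 3.64e-24; 8 and 9 adjusted over the list alone, 11 and 7 with the block). Of 16 glucocorticoid-inducible genes, 3 rose with each, SGK1 included (adjusted p = 2.63e-13 and 4.51e-20; 5 and 5 adjusted over the list alone, 8 and 5 with the block). Of 13 inflammatory cytokine, chemokine and adhesion genes, 2 rose with each, IL6 and CXCL2 (adjusted p = 1.42e-06 and 3.36e-10). Of 20 MAP kinase feedback inhibitors, 3 rose with each, among them SPRY2 (1.06 and 1.12) and DUSP4 (0.65 and 0.74), with adjusted p = 2.22e-06 and 7.29e-09 (4 and 4 adjusted over the list alone).

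Other lists at 1 h held few called members. TOB1, an antiproliferative gene, rose by 0.68 and 0.70 as the only 1 of 12 cell cycle inhibitors; the list adjusted p was 0.00181 with Ind/GSK (adjusted p = 0.14 with an estimated correlation) and 9.95e-06 with GS-5759. BHLHE40, a clock repressor, rose 2.68-fold and 3.06-fold as the only called 1 of 14 clock genes, with list adjusted p = 0.141 and 0.0504 (block 0.0113 for GS-5759) and an Ind/GSK median of -0.09 beside a mean of 0.06. Adjusted over the list alone, 1 clock gene rose and 1 fell with Ind/GSK and 2 rose with GS-5759; the block gave 2 and 1, and 2. POSTN, an extracellular matrix gene, rose by 0.55 with Ind/GSK, though its groups overlapped. Its list of 21 matrix and TGF-beta response genes had adjusted p = 0.00577 and 0.0334, with a median of -0.06 and a mean of 0.02 for Ind/GSK; after 75th percentile centring adjusted p was 0.161 and 0.0774. None of 23 interferon-stimulated genes was called; adjusted p was 0.000863 upward with Ind/GSK (adjusted p = 0.492 with an estimated correlation, 0.316 after 75th percentile centring) and 0.693 with GS-5759. None of 11 fibroblast markers was called; adjusted p was 0.0294 upward with Ind/GSK around a median of -0.07, 0.161 after 75th percentile centring and 0.203 with the block, and 0.693 with GS-5759. Of these, 1 rose with Ind/GSK adjusted over the list alone, as with the block. The block also gave 2 risen and 2 fallen matrix genes and 2 risen cell cycle inhibitors with Ind/GSK, and 1 risen matrix gene with GS-5759.

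NR4A3 also led the Ind/GSK response at 2 h. It rose by 5.46 ± 0.57 (mean signal 27.4 ± 12.9 SD to 2010 ± 969 SD). Its vehicle signal lay below the filter level of 75.42, so this size depends on the added 16, and its other probe set gave 4.28. NR4A2 rose by 4.14 ± 0.73 (17.6-fold). LINC00473, a long non-coding RNA known to be induced by cAMP, rose by 3.36 ± 0.30 (10.3-fold). CRISPLD2, a secreted protein known to be induced by glucocorticoids in the airway, rose by 2.95 ± 0.39 (7.74-fold); another probe set of that gene gave -0.15. IL6 rose by 2.75 ± 0.48 (6.74-fold), SIK1 by 2.58 ± 0.38 (5.99-fold) and PDE4D, a target of both PDE4 inhibitors, by 2.41 ± 0.44 (5.33-fold; 1.86, 1.98, 0.06 and 2.31 for its other probe sets). SGK1 rose by 2.39 ± 0.21 (5.26-fold), PRDM1 by 2.27 ± 0.26 (4.82-fold) and CD200, an immune inhibitory surface protein, by 2.12 ± 0.30 (4.36-fold). EGR1, an immediate early transcription factor, fell by 1.59 ± 0.19 to 0.333 of vehicle, and TXNIP, a thioredoxin inhibitor, by 1.46 ± 0.22 to 0.364. The cell cycle genes BORA, CCNF and HJURP fell by 0.94 ± 0.12, 0.87 ± 0.15 and 0.76 ± 0.13. Adjusted p was 3.94e-08 for NR4A3, 1.16e-09 for LINC00473, 0.000546 for PDE4D and 5.2e-07 for EGR1.

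Limma called 503 genes with Ind/GSK at 2 h: 193 risen, 57 of them at least 2-fold, and 310 fallen, 2 of them at least 2-fold; 1962 had an unadjusted p under 0.05. Quantile normalization gave 222 risen and 229 fallen, and the replicate block 542 and 1166. Without Ind/GSK replicate 3 the count was 268. Of 38 refitted genes, 25 were called in all 8 leave-1-out fits; PDE4B, CEBPD, CXCL2, SPRY2, AJUBA, AURKA, TTK, CDC25C, BUB1B, BTG1, BHLHE40, CIART and YWHAZ were not. TTK and CDC25C were called under neither of the other scalings.

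With GS-5759 at 2 h NR4A3 rose by 5.53 ± 0.57 (mean signal 2170 ± 1150 SD, 4.39 for its other probe set) and NR4A2 by 4.24 ± 0.73 (18.9-fold). LINC00473 rose by 3.47 ± 0.30 (11.1-fold), CRISPLD2 by 2.97 ± 0.39 (7.83-fold, -0.17 for its other probe set) and IL6 by 2.86 ± 0.48 (7.26-fold). SIK1 rose 6.70-fold, SGK1 5.66-fold, PDE4D 5.38-fold (2.43 ± 0.44; 2.02, 2.09, 0.09 and 2.31 for its other probe sets), PRDM1 5.35-fold and RGS2 4.59-fold. PDE4B, another PDE4 gene, rose by 1.01 ± 0.24 (2.01-fold), beside 0.93 ± 0.24 (1.91-fold) with Ind/GSK. TXNIP fell by 1.48 ± 0.22, EGR1 by 1.41 ± 0.19, CCNF by 0.91 ± 0.15, BORA by 0.90 ± 0.12 and the probe set annotated as Igk by 0.74 ± 0.15. Adjusted p was 1.42e-08 for NR4A3, 0.000481 for PDE4D and 0.0102 for PDE4B. Limma called 350 genes: 230 risen, 65 of them at least 2-fold, and 120 fallen, 2 of them at least 2-fold; 1745 had an unadjusted p under 0.05. The split was 210 risen and 277 fallen after 75th percentile centring, 220 and 233 after quantile normalization, and 760 and 584 with the replicate block. Of 34 refitted genes, 26 were called in all 8 leave-1-out fits; PDE4B, CEBPD, SPRY2, AURKA, DNAJB9, NFIL3, BHLHE40 and DNAJB1 were not.

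cAMP-CREB target genes held the largest share of called members at 2 h. Of the 17, 11 rose with each treatment, among them NR4A1 (1.91 and 2.03), PDE4D and CREM (0.43 with Ind/GSK), with medians of 0.93 and 1.08 (camera adjusted p = 5.52e-36 and 2.67e-31; 14 and 14 adjusted over the list alone). NR4A1 has 2 other probe sets, of which 1 gave -0.11 and -0.17 and the other 2.12 and 2.22. Of 18 effector genes, 7 and 8 rose, among them CD200 (2.12 with each), RGS2 and DUSP1 (0.59 and 0.63), with adjusted p = 3.08e-16 and 1.15e-14 (9 and 9 adjusted over the list alone, 11 and 13 with the block). Of 16 glucocorticoid-inducible genes, 5 rose with each, among them SGK1, CRISPLD2 and CEBPD (0.67 and 0.80), a transcription factor gene (adjusted p = 3.41e-15 and 3.26e-13; 5 and 6 adjusted over the list alone, 9 and 10 with the block). IL6, CXCL2 (1.68 and 1.87, with -0.06 and -0.05 for its other probe set) and IL15 (0.83 and 0.90), a cytokine gene, were the 3 of 13 inflammatory genes that rose with each (adjusted p = 3.6e-05 and 5.47e-05; 4 and 4 adjusted over the list alone). Of 20 immediate early genes, 6 rose with each and EGR1 fell, with adjusted p = 7.04e-07 and 8.18e-07; FOSL2 rose by 1.06 and 1.13. Adjusted over the list alone, 6 and 8 rose and 2 and 2 fell; the block gave 10 risen with each and 5 and 4 fallen. Of 20 MAP kinase feedback inhibitors, 3 rose with each, DUSP4 by 0.84 and 0.94 and SPRY2 by 0.84 and 0.86 (adjusted p = 0.00131 and 0.0042). For that list adjusted p = 0.133 and 0.197 with an estimated correlation; 3 and 4 rose adjusted over the list alone and 5 and 6 with the block. The median of that list with Ind/GSK was -0.01, opposite in sign to its mean and its camera direction.

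Some mitotic genes fell at 2 h. Of 23 G2/M and mitosis genes, 4 fell with Ind/GSK, AURKA (-0.61), TTK (-0.38), CDC25C (-0.37) and BUB1B (-0.31), and 1 with GS-5759, AURKA (-0.59). These encode mitotic kinases, a phosphatase and a checkpoint protein. The list medians were -0.23 and -0.17 (adjusted p = 1.41e-07 and 3.59e-07; adjusted p = 0.133 and 0.155 with an estimated correlation), with 7 and 1 fallen adjusted over the list alone and 11 and 9 with the block. Of 12 cell cycle inhibitors, TOB1 (0.67 and 0.66) and BTG1 (0.48 and 0.61) rose with each, with adjusted p = 0.00262 and 0.00375 (adjusted p = 0.133 and 0.155 with an estimated correlation). None of 22 G1/S and DNA replication genes was called (adjusted p = 0.412 and 0.736; 0 and 0 adjusted over the list alone), and the block gave 1 fallen with Ind/GSK. It also gave 4 risen cell cycle inhibitors with GS-5759.

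Further lists at 2 h had 0 to 2 called members with each treatment. PDE4D and PDE4B were the 2 of 25 cAMP breakdown and β2-receptor regulation genes that rose with each treatment (adjusted p = 0.0805 and 0.0946, or 0.0335 and 0.0372 with the block, which gave 3 and 4 risen). Of 18 YAP and SRF target genes, CCN2, a matricellular protein, rose by 1.25 ± 0.27 and 1.35, and AJUBA fell by 0.34 with Ind/GSK (adjusted p = 0.834 and 0.761; 2 fallen with GS-5759 adjusted over the list alone; block 2 risen and 5 fallen, and 3 and 3). PLAUR, the urokinase receptor, rose by 0.53 and 0.56 as the only matrix gene called (adjusted p = 0.0811 and 0.144, block 0.0191 and 0.0102, with 2 and 3 risen). HERPUD1, of the unfolded protein response, rose by 0.48 and 0.55, and DNAJB9 by 0.33 with GS-5759 (list adjusted p = 0.252 and 0.209; 2 risen with Ind/GSK adjusted over the list alone and 3 with the block). Among clock genes BHLHE40 rose by 0.95 and 1.15, NFIL3 by 1.19 with GS-5759, and CIART fell by 0.61 with Ind/GSK (adjusted p = 0.633 and 0.844; adjusted over the list alone 2 risen and 3 fallen, and 2 and 2). None of 8 EGF receptor ligands and receptors was called (adjusted p = 0.033 upward with Ind/GSK, adjusted p = 0.094 with an estimated correlation; 0.0946 with GS-5759, block 0.0107; block counts 2 and 3 risen). None of 12 NRF2 target genes was called (adjusted p = 0.289 and 0.473); adjusted over the list alone, 1 rose and 1 fell with Ind/GSK, and the block gave 1 and 2. None of 12 cholesterol synthesis genes was called at 2 h (adjusted p = 0.633 and 0.974; the block gave 2 fallen with Ind/GSK and 1 risen with GS-5759). None of 23 interferon-stimulated genes was called (adjusted p = 0.119 and 0.0946, block 0.0411 upward for GS-5759).

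CRISPLD2 and CSGALNACT1 led the Ind/GSK response at 6 h. CRISPLD2 rose by 3.04 ± 0.39 (8.22-fold, -0.04 for its other probe set) and CSGALNACT1, a chondroitin sulfate synthesis enzyme, by 2.88 ± 0.22 (7.34-fold; mean signal 133 ± 30.6 SD to 1110 ± 406 SD; 0.01 for its other probe set). NR4A3 rose by 2.67 ± 0.57 (1.16 for its other probe set), a size that depends on the added 16, as its mean vehicle signal was 7.42, LINC00473 by 2.35 ± 0.30 (5.11-fold), SMOC1, a matricellular protein, by 2.34 ± 0.60 (5.06-fold) and LPL, lipoprotein lipase, by 2.08 ± 0.55 (4.23-fold). PDE7B, a cAMP phosphodiesterase, rose by 2.08 ± 0.21 (4.23-fold), and PDE4D by 1.84 ± 0.44 (3.58-fold; 1.44, 1.40, 0.17 and 2.24 for its other probe sets). SLC7A2, a cationic amino acid transporter, rose by 1.99 ± 0.18 (3.97-fold), STEAP4, a metalloreductase, by 1.98 ± 0.29 (3.94-fold) and GALNT15, a glycosyltransferase, by 1.86 ± 0.27 (3.62-fold). EGR1 fell by 1.28 ± 0.19 to 0.411 of vehicle, GASK1B by 0.97 ± 0.28, F3, tissue factor, by 0.78 ± 0.16, RBM12 by 0.76 ± 0.12 and C1orf198 by 0.73 ± 0.09. Adjusted p was 2.06e-11 for CSGALNACT1, 0.0111 for PDE4D, 0.0228 for LPL and 0.0426 for GASK1B.

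Limma called 537 genes with Ind/GSK at 6 h: 148 risen, 31 of them at least 2-fold, and 389 fallen, 1 of them at least 2-fold; 2106 had an unadjusted p under 0.05. The split was 195 risen and 250 fallen after 75th percentile centring, 218 and 276 after quantile normalization, and 675 and 1892 with the replicate block. Leaving out 1 array gave 240 genes without Ind/GSK replicate 3, 328 without vehicle replicate 1 and 330 without vehicle replicate 4. Of 38 refitted genes, 23 were called in all 8 such fits; SMOC1, LPL, GASK1B, PDE4D, SIK1, RGS2, SGK1, CEBPD, FOSL2, AJUBA, MKI67, KIF20A, CCNB2, BUB1B and DNAJB1 were not.

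GS-5759 at 6 h raised CRISPLD2 by 3.07 ± 0.39 (8.39-fold, -0.21 for its other probe set) and CSGALNACT1 by 2.86 ± 0.22 (7.24-fold; mean signal 1080 ± 331 SD; -0.15 for its other probe set). NR4A3 rose by 2.47 ± 0.57 (1.08 for its other probe set), a size with the same limit, SMOC1 by 2.30 ± 0.60 (4.92-fold), LINC00473 by 2.16 ± 0.30 (4.48-fold), LPL by 2.06 ± 0.55 (4.16-fold) and PDE7B by 2.04 ± 0.21 (4.10-fold). SLC7A2 rose 3.83-fold, STEAP4 3.77-fold, GALNT15 3.47-fold and PDE4D 3.23-fold (1.69 ± 0.44; 1.26, 1.24, 0.13 and 2.04 for its other probe sets). EGR1 fell by 0.89 ± 0.19, F3 by 0.70 ± 0.16, MVD, a cholesterol synthesis enzyme, by 0.58 ± 0.13, GDF3 by 0.58 ± 0.15 and C1orf198 by 0.57 ± 0.09. Adjusted p was 2.61e-11 for CSGALNACT1, 0.0379 for PDE4D and 0.0342 for GDF3. Limma called 228 genes: 149 risen, 25 of them at least 2-fold, and 79 fallen, none at least 2-fold; 1790 had an unadjusted p under 0.05. After 75th percentile centring 183 of 311 called genes were fallen; quantile normalization gave 155 risen and 156 fallen, and the replicate block 866 and 660. Leaving out 1 array gave 97 genes without GS-5759 replicate 1, 134 without replicate 2, 146 without replicate 3, 104 without vehicle replicate 2 and 121 without vehicle replicate 3. Of 26 refitted genes, 10 were called in all 8 such fits; NR4A3, SMOC1, LPL, EGR1, F3, GDF3, PDE4D, AKAP12, DUSP1, CD200, IL15, DUSP4, VCL, LSS, SQLE and TXNRD1 were not.

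Some cholesterol synthesis genes fell at 6 h with both treatments. Of the 12, 4 fell with each: MVD (-0.71 ± 0.13 with Ind/GSK), LSS (-0.62 ± 0.12 and -0.49), MVK (-0.58 ± 0.08 and -0.52) and SQLE (-0.31 ± 0.07 and -0.27), all enzymes of the mevalonate or sterol pathway. The list medians were -0.29 and -0.24 (camera adjusted p = 3.43e-08 and 2e-07; 7 and 5 fallen adjusted over the list alone, 8 and 6 with the block). MVK has 3 other probe sets, which gave -0.88, -1.03 and 0.01 with Ind/GSK and -0.71, -0.88 and -0.20 with GS-5759. Of 17 cAMP-CREB targets, 7 and 5 rose, SIK1 by 1.53 with Ind/GSK, with medians of 0.54 and 0.52 (adjusted p = 9.89e-15 and 3.04e-08; 9 and 7 adjusted over the list alone, 11 and 10 with the block). PDE4D and PDE7B were the 2 of 25 cAMP breakdown genes that rose with each (adjusted p = 0.00518 and 0.00983; 3 and 3 adjusted over the list alone, 4 and 6 with the block). Of 18 effector genes, 4 and 3 rose, CD200 by 1.42 and 1.22 and DUSP1 by 0.51 and 0.39 (adjusted p = 5.79e-09 and 1.24e-06; 4 and 5 adjusted over the list alone, 10 and 7 with the block). CD200 and DUSP1 values overlapped between GS-5759 and vehicle arrays. Of 16 glucocorticoid-inducible genes, 5 and 2 rose, SGK1 by 0.84 and CEBPD by 0.74 with Ind/GSK (adjusted p = 3.04e-09 and 1.24e-06; 6 and 5 adjusted over the list alone, 9 and 9 with the block). For GS-5759 that list had adjusted p = 0.0828 with an estimated correlation.

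Of 23 G2/M genes, 5 fell with Ind/GSK at 6 h, among them the proliferation marker MKI67 (-0.50), KIF20A (-0.42), CCNB2 (-0.42, with 0.28 for its other probe set) and NUSAP1 (-0.19), and none with GS-5759. The adjusted p was 8.71e-05 and 0.0244 (adjusted p = 0.293 and 0.597 with an estimated correlation), with 8 fallen for Ind/GSK adjusted over the list alone and 10 and 3 with the block. IL15 rose by 0.76 and 0.58 as the only inflammatory gene called, with list adjusted p = 0.00561 for Ind/GSK (adjusted p = 0.107 with an estimated correlation) and 0.168 for GS-5759. The block gave 4 and 3 risen inflammatory genes. Of immediate early genes, 2 and 1 rose and EGR1 fell (adjusted p = 0.0126 and 0.0283; adjusted p = 0.293 and 0.481 with an estimated correlation; 4 and 2 risen adjusted over the list alone, 5 and 5 with the block). DUSP4 rose by 0.71 and 0.52 among 2 MAP kinase feedback inhibitors that rose with each (adjusted p = 0.0125, adjusted p = 0.293 with an estimated correlation, and 0.119). Of YAP and SRF targets, F3, AJUBA (-0.40) and VCL (-0.28), a focal adhesion protein, fell with Ind/GSK and F3 and VCL (-0.15) with GS-5759 (adjusted p = 0.251 and 0.168; block 3 risen and 5 fallen, and 0 and 4). None of the cell cycle inhibitors was called, 2 with Ind/GSK adjusted over the list alone; adjusted p was 0.0264 (adjusted p = 0.293 with an estimated correlation) and 0.119 (block 0.0499), and the block gave 4 and 3 risen. TRIB3 (-0.31 with Ind/GSK, unfolded protein response) and TXNRD1 (-0.27 and -0.22, NRF2 targets) fell in lists with adjusted p of 0.308 and 0.198, and 0.765 and 0.757. With the block 2 and 1 stress response genes and 5 and 4 NRF2 targets fell. None of the matrix genes was called at 6 h (adjusted p = 0.0303, or 0.064 after 75th percentile centring, and 0.168, block 0.0411), where the block gave 5 and 4 risen. None of the interferon-stimulated genes was called at 6 h, medians -0.31 and -0.16 (adjusted p = 0.0892 and 0.168, block 0.0111 and 0.032, with 4 fallen for Ind/GSK).

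**Figure D1:**
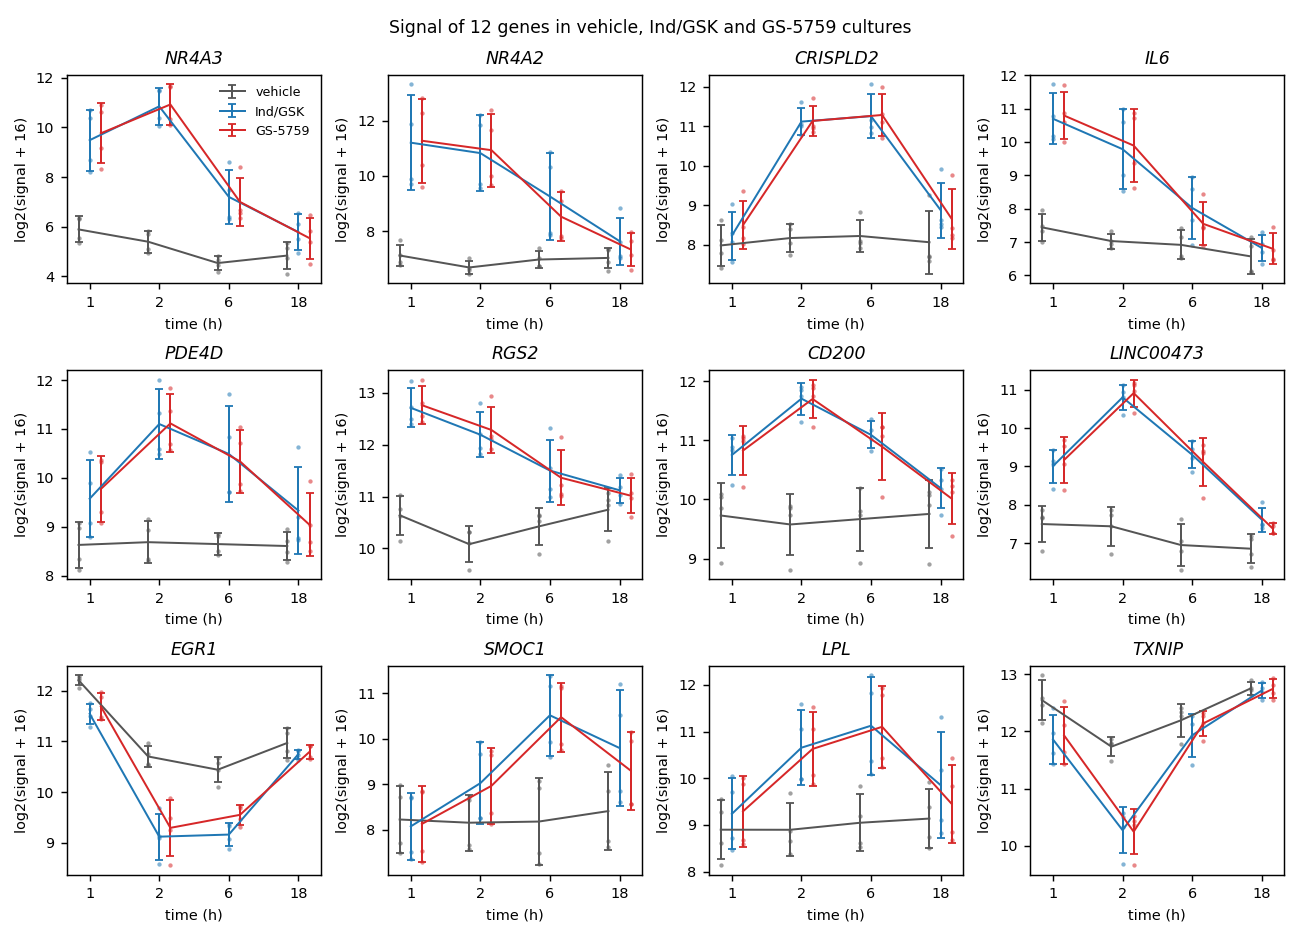
Signal of 12 genes (NR4A3, NR4A2, CRISPLD2, IL6, PDE4D, RGS2, CD200, LINC00473, EGR1, SMOC1, LPL and TXNIP) as log2(signal + 16) at 1, 2, 6 and 18 h. Points are single arrays, lines group means and bars SD (n = 4), in grey for vehicle, blue for Ind/GSK and red for GS-5759.

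Few genes were called at 18 h. With Ind/GSK IGLC1 rose by 0.55 ± 0.11 (1.47-fold), P4HTM, a transmembrane prolyl hydroxylase, by 0.32 ± 0.04 (1.25-fold) and DDRGK1 by 0.25 ± 0.05. CLIC5, a chloride channel family gene, fell by 1.05 ± 0.22 to 0.483 of vehicle (-0.39 and -0.08 for its other probe sets), BEST2 by 0.66 ± 0.13, TNS1, tensin 1, by 0.60 ± 0.10 and TMEM158 by 0.54 ± 0.10. Adjusted p ran from 0.000143 for P4HTM to 0.0432 for CLIC5, which lost its call after quantile normalization. These were the 7 genes limma called; 849 had an unadjusted p under 0.05, quantile normalization gave 5 risen and 3 fallen, and the block 74 and 197. Leaving out 1 array gave 2 genes without Ind/GSK replicate 1, 3 without Ind/GSK replicate 3, 3 without vehicle replicate 1, 3 without vehicle replicate 2, 1 without vehicle replicate 3 and 12 without vehicle replicate 4; only P4HTM was called in all 8 fits. For GS-5759 limma called 0 genes; 462 had an unadjusted p under 0.05, 75th percentile centring and quantile normalization each gave 1, and the block 14 risen and 7 fallen. Without GS-5759 replicate 3 there were 2 and without vehicle replicate 4 there were 3.

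No member of any fixed list was called at 18 h, and limma and camera differed there. Effector genes had a median of 0.12 and adjusted p = 0.00219 with Ind/GSK (adjusted p = 0.311 with an estimated correlation) and 0.231 with GS-5759 (block 0.00981); the block gave 3 and 1 risen. cAMP-CREB targets had a median of 0.20 with Ind/GSK, NR4A3 among them, and adjusted p = 0.0343 (adjusted p = 0.907 with an estimated correlation, 0.159 after 75th percentile centring). Interferon-stimulated genes had medians of -0.42 and -0.38 (adjusted p = 0.00164 and 1.15e-07; adjusted p = 0.952 and 0.902 with an estimated correlation; the block gave 5 fallen for Ind/GSK). YAP and SRF targets had medians of -0.20 and -0.12 (adjusted p = 0.00164 and 0.00759; adjusted p = 0.907 and 0.902 with an estimated correlation), 1 fallen for Ind/GSK adjusted over the list alone and 3 with the block. G1/S genes had adjusted p = 0.046 downward with Ind/GSK (adjusted p = 0.952 with an estimated correlation, 0.105 with the block). Glucocorticoid-inducible genes had adjusted p = 0.0653 with Ind/GSK, 0.00358 with the block. With Ind/GSK, adjusted over the list alone, 1 cAMP breakdown gene and 1 matrix gene rose and 1 basal marker fell. Reference genes had adjusted p = 0.0905 with GS-5759, 0.0277 with the block.

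Lists marking other cell types, ion transport and sample quality held few called genes in the treatment comparisons. None of 8 airway basal and squamous epithelial markers was called: at 2 h adjusted p was 0.53 and 0.761. None of 7 airway ion transport and mucin genes was called, with adjusted p = 0.319 and 0.844 at 2 h. None of 5 leukocyte markers was called, with adjusted p = 0.946 and 0.473. Adjusted over the list alone these 3 lists gave 0 as well at 2 h. Of 8 heat shock genes, DNAJB1, a co-chaperone, fell by 0.30 and 0.23 at 2 h and by 0.26 with Ind/GSK at 6 h (adjusted p = 0.19, 0.553 and 0.161; block 2, 1 and 3 fallen). Of 11 reference genes, YWHAZ fell by 0.21 with Ind/GSK at 2 h, with -0.14, -0.13, -0.09 and 0.01 for its 4 other probe sets and no call after quantile normalization (list adjusted p = 0.504 and 0.612; block 1 risen and 3 fallen). At 1 h the reference list had adjusted p = 0.356 with Ind/GSK, and with GS-5759 a median of -0.07 and adjusted p = 0.0266 (0.0774 after 75th percentile centring, 0.433 after quantile normalization). Of the ciliated and club cell markers only DNAH5, DNAI1 and BPIFA1 passed the signal filter (mean log2 7.03, 7.35 and 7.24), and of the endothelial markers only PECAM1, VWF, EGFL7 and ROBO4 (9.06, 6.53, 7.16 and 6.90). Both lists were too small to test, and 0 of their members were called, where limma adjusted over all genes.

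Of the PDE4 genes that both treatments target, PDE4D and PDE4B alone rose. PDE4A had changes of -0.15, 0.07, 0.02 and 0.08 with Ind/GSK and of -0.06, 0.09, 0.11 and 0.09 with GS-5759 at 1, 2, 6 and 18 h. PDE4D at 1 h had 0.94 (adjusted p = 0.25, or 0.000867 with the block) and 1.14 (0.792, or 8.48e-05 with the block), and at 18 h 0.72 (0.933, or 0.0313 with the block) and 0.43. PDE4B at 1 h had 0.74 (0.0824, or 0.00796 with the block) and 0.81 (0.284, or 0.0112 with the block), and at 6 h 0.44 and 0.35. Centring on the 75th percentile gave PDE4B a call with Ind/GSK at 1 h, at 0.86. PDE4C was not analysed here.

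GS-5759 at 10 nM was compared with Ind/GSK, both at 10 nM, at each time. No gene differed between the treatments at 1, 2, 6 or 18 h by limma; 855, 273, 468 and 54 had an unadjusted p under 0.05, and the block gave 0 at each. After 75th percentile centring 2 genes differed at 1 h. Of genes called in either treatment, 264 of 266 changed with the same sign at 1 h, 587 of 587 at 2 h, 593 of 594 at 6 h and 7 of 7 at 18 h. As these genes were picked for a call and both responses share vehicle arrays, part of this follows without a shared effect, and so it does for the slopes below. The largest single differences were those of DAB1 (0.42) at 1 h, TMC5 (0.45) at 2 h, HGD (0.42) at 6 h and CLIC5 (0.38) at 18 h. The 95% interval of the difference lay within 2-fold for 262, 583, 589 and 7 of these genes (all with the block). Among genes changed at least 2-fold it did for 15 of 19 at 1 h and 64 of 68 at 2 h (not for NR4A2, NR4A3, IL6 or CXCL2). At 6 h it did for 27 of 32 (not for LPL, PDE4D, SIK1, NR4A3 or SMOC1). The slopes of GS-5759 on Ind/GSK in these genes were 1.059, 1.036 and 0.953. A difference smaller than the interval was not excluded, and a p above the threshold does not show that the treatments act alike.

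Overlap of the called genes exceeded that of independent lists, which share no arrays. Risen genes shared by both treatments numbered 35 at 1 h, 184 at 2 h and 116 at 6 h (0.167, 3.08 and 1.53 for independent lists), and fallen genes 2, 82 and 55 (0.0276, 2.58 and 2.13). With the replicate block they numbered 125, 514 and 568 risen (3.28, 28.6 and 40.6 for independent lists) and 51, 415 and 530 fallen (8.07, 47.3 and 86.7). NR4A2, IL6 and SGK1 were among those shared at 1 h and LINC00473 and PDE4D at 2 h. Both treatments share vehicle arrays, and how much of the overlap this gives was not measured. Pearson correlation over all genes was 0.80, 0.921, 0.874 and 0.85 at 1, 2, 6 and 18 h (Spearman 0.631, 0.824, 0.777 and 0.819), where unchanged genes with shared vehicle arrays simulated to 0.502, 0.499, 0.504 and 0.498. The covariance was 0.0225, 0.0429, 0.0337 and 0.0148, against 0.0205, 0.0205, 0.0208 and 0.0205 simulated. That simulation took the spread without the pairing by replicate number, so the covariances decide nothing here. With each treatment set against different vehicle arrays the correlation averaged 0.09, 0.325, 0.262 and -0.089 over 6 assignments. It ranged from -0.244 to 0.367, 0.057 to 0.477, -0.026 to 0.455 and -0.383 to 0.115. Replicate numbers were taken to pair the arrays, and vehicle arrays of different numbers would then set the responses apart. The value without a shared effect was not measured, and these correlations decide nothing here. With shared vehicle arrays, leaving out 1 array took the correlation as low as 0.574, 0.779, 0.708 and 0.533.

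**Figure D2:**
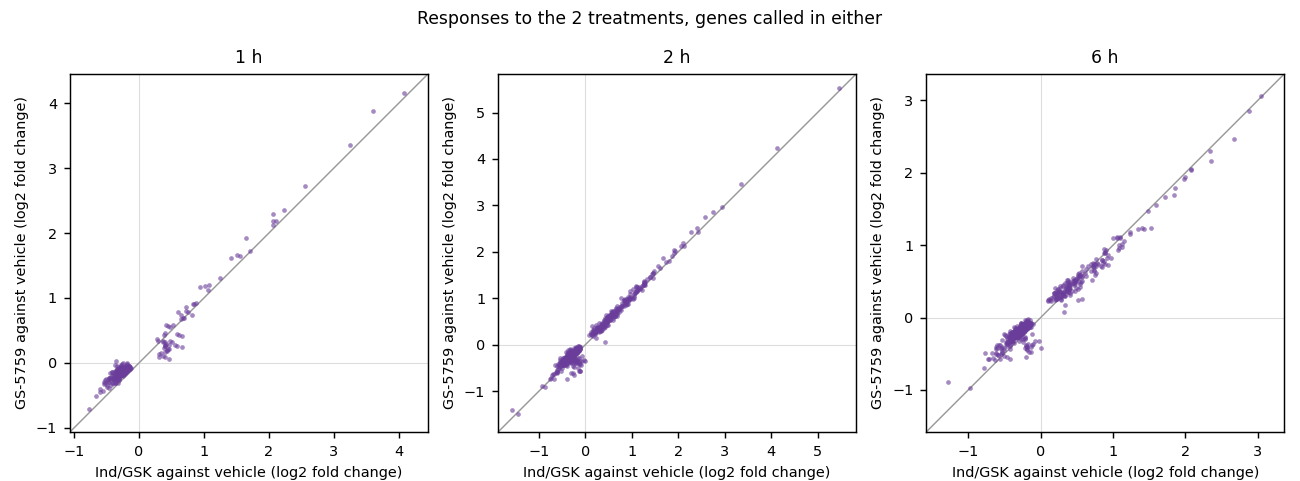
Log2 change with GS-5759 against log2 change with Ind/GSK for genes called in either treatment at 1, 2 and 6 h (266, 587 and 594 genes). Each point is a gene (n = 4 arrays per group), and the line marks equal change.

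Averaged over the 4 times, small differences between the treatments were called. PALMD, encoding palmdelphin, was lower with GS-5759 by 0.47 ± 0.07 and MEFV, the pyrin gene, by 0.34 ± 0.06, with LINC01366 (-0.31), HES5 (-0.29) and LINC02361 (-0.26). ARAP2 was higher by 0.18 ± 0.04, PHF2, a histone demethylase, by 0.17 ± 0.03, STRN4 by 0.16, ZKSCAN5 by 0.14 and MCRS1 by 0.11. Adjusted p was 0.000356 for PALMD, 0.0185 for MEFV and 0.0474 for ARAP2. Other probe sets gave -0.08 and -0.07 for ARAP2 and 0.03 for LINC01366. Limma called 13 genes, 6 higher and 7 lower, none at least 2-fold; 2374 had an unadjusted p under 0.05. The direction split differed between settings: 0 higher and 84 lower after 75th percentile centring, 0 and 35 after quantile normalization, and 1890 and 170 with the replicate block. A shift of all genes alike moves such a split by construction. Without replicate 1, 2, 3 or 4 the count was 0, 2, 2 or 4, and none of the 10 named genes was called in all 4 fits. No list member was called in the direct comparisons at single times. By camera at 6 h, cAMP-CREB targets had a median of -0.10 (adjusted p = 0.00222, adjusted p = 0.486 with an estimated correlation, 0.0519 after 75th percentile centring). At 1 h interferon-stimulated genes had adjusted p = 0.000226 downward (adjusted p = 0.912 with an estimated correlation, 0.641 after 75th percentile centring) and fibroblast markers 0.0317 (adjusted p = 0.078 with an estimated correlation, 0.298 with the block). At 18 h effector genes had adjusted p = 0.00685 (adjusted p = 0.18 with an estimated correlation), cAMP-CREB targets 0.0375 and glucocorticoid-inducible genes 0.0482 (for each adjusted p = 0.845 with an estimated correlation), none passing after 75th percentile centring. Ion transport genes had 0.0785 and leukocyte markers 0.159 there, or 0.0493 and 0.0266 with the block. Over the 4 times no list member was called, where 1 cAMP-CREB target was lower and 2 YAP and SRF targets and 1 heat shock gene were higher adjusted over the list alone.

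Responses of later genes grew between 1 and 2 h. CRISPLD2 rose by a further 2.58 ± 0.48 (mean of both treatments against vehicle, -0.09 for its other probe set), LINC00473 by 1.83 ± 0.37, SLC7A2 by 1.41 ± 0.22, SIK2, a salt-inducible kinase, by 1.24 ± 0.25 and ZNF462 by 1.18 ± 0.23. Adjusted p was 0.00441 for CRISPLD2 and 0.0135 for LINC00473. Limma called 19 genes, all higher and 5 of them at least 2-fold; 1131 had an unadjusted p under 0.05. The split was 17 higher and 10 lower after 75th percentile centring, 17 and 7 after quantile normalization, and 279 and 64 with the block. Without replicate 1, 2, 3 or 4 the count was 6, 5, 58 or 80, and of 5 refitted genes SLC7A2 alone was called in all 4 fits. IL15 was the 1 inflammatory gene called, at 0.92 (2 with the block). G2/M genes had a median of -0.12 (adjusted p = 0.000571, adjusted p = 0.812 with an estimated correlation), and cAMP-CREB targets adjusted p = 0.13 (0.00885 with the block, 0.00328 after 75th percentile centring), with 0 called, 1 adjusted over the list alone and 4 with the block.

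Between 2 and 6 h the responses of CSGALNACT1 (2.83 ± 0.27, 0.16 for its other probe set), PDE7B (2.05 ± 0.26), GALNT15 (1.33), TXNIP (1.31) and PITPNC1 (1.09) rose. Those of NR4A3 (-2.93 ± 0.70), SGK1 (-1.68 ± 0.26), ZNF331 (-1.43), PRDM1 (-1.30) and ITPRIP (-1.26) fell. The size for NR4A3 depends on the added 16, as its vehicle signals averaged 27.4 and 7.42. Adjusted p was 1.55e-08 for CSGALNACT1 and 0.0363 for NR4A3. Limma called 82 genes, 45 higher and 37 lower, 5 and 11 of them at least 2-fold; 1117 had an unadjusted p under 0.05, and the block gave 319 and 385. Without replicate 1, 2 or 4 the count was 38, 7 or 13, and CSGALNACT1, PDE7B and SGK1 were called in all 4 fits. Responses of the immediate early genes NR4A3 and FOSL2 (-0.65) fell (adjusted p = 0.0108, or 0.474 with an estimated correlation). Adjusted over the list alone 4 fell, 6 with the block. NR4A3 was the 1 cAMP-CREB target that fell (adjusted p = 6.57e-09, adjusted p = 0.0855 with an estimated correlation; 7 adjusted over the list alone). Cholesterol synthesis genes had a median of -0.21 (adjusted p = 1.89e-07, adjusted p = 0.0855 with an estimated correlation; 0 called, 3 adjusted over the list alone, 6 with the block). Interferon-stimulated genes had a median of -0.38 (adjusted p = 0.00151, adjusted p = 0.715 with an estimated correlation). SGK1 was the 1 glucocorticoid-inducible gene that fell (adjusted p = 0.0373, adjusted p = 0.715 with an estimated correlation, 0.0617 with the block; 2 adjusted over the list alone), and TOB1 (-0.46) the 1 cell cycle inhibitor. Of effector genes 0 were called, 2 adjusted over the list alone and 4 with the block (adjusted p = 0.0133, adjusted p = 0.307 with an estimated correlation). EGF receptor ligands and receptors had adjusted p = 0.104, 0.0238 with the block.

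Between 6 and 18 h the responses of CSGALNACT1 (-2.63 ± 0.27), CRISPLD2 (-2.35 ± 0.48), SLC7A2 (-1.64 ± 0.22), LINC00473 (-1.62) and GALNT15 (-1.48) fell. Those of RBM12 (0.78), MVD (0.73), MVK (0.60), ZNF143 (0.53) and FBXO16 (0.53) rose. Adjusted p was 1.16e-07 for CSGALNACT1 and 0.0116 for CRISPLD2. Other probe sets gave 0.10 for CRISPLD2, 0.07 for CSGALNACT1, and 0.87, 1.03 and -0.07 for MVK. Limma called 52 genes, 25 higher and 27 lower, of which 9 of the lower at least 2-fold; 1149 had an unadjusted p under 0.05. The split was 101 higher and 49 lower after 75th percentile centring, 76 and 51 after quantile normalization, and 421 and 411 with the block. Without replicate 1, 2, 3 or 4 the count was 11, 7, 81 or 8, and CSGALNACT1 and SLC7A2 were called in all 4 fits. MVD and MVK were the 2 cholesterol synthesis genes that rose (adjusted p = 3.82e-06, adjusted p = 0.0846 with an estimated correlation; 3 adjusted over the list alone, 4 with the block). PDE7B (-1.36) and DUSP4 (-0.69) were the only members of their lists that fell (adjusted p = 0.0105 and 0.00976; adjusted p = 0.0667 and 0.319 with an estimated correlation), with 1 and 2 adjusted over the list alone and 5 and 2 with the block. CRISPLD2 was the 1 effector and glucocorticoid-inducible gene that fell (adjusted p = 0.000461 and 1.38e-05; adjusted p = 0.0667 and 0.137 with an estimated correlation; 2 and 2 adjusted over the list alone, 5 and 7 with the block). No cAMP-CREB target was called, though adjusted p was 2.19e-07 downward (adjusted p = 0.0667 with an estimated correlation; 3 adjusted over the list alone, 9 with the block). G2/M genes had a median of 0.20 (adjusted p = 3.48e-05, adjusted p = 0.319 with an estimated correlation), with 0 called and 6 with the block. Cell cycle inhibitors had adjusted p = 0.00976 downward (adjusted p = 0.293 with an estimated correlation), and immediate early and matrix genes 0.13 and 0.23 (block 0.0404 and 0.0264).

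Risen genes overlapped between neighbouring times up to 6 h. With Ind/GSK 34 were shared by 1 and 2 h and 62 by 2 and 6 h (0.871 and 1.98 expected), SIK1 and LINC00473 included. With GS-5759 36 of 37 and 56 of 230 were (0.591 and 2.38 expected). Shared falls numbered 70 and 39 with Ind/GSK (4.28 and 8.37 expected) and 0 and 7 with GS-5759 (0.0167 and 0.658 expected). Array scaling may give part of the 70. Of 258 genes risen with both treatments at 1 or more times, 17 had their highest mean response at 1 h, 152 at 2 h, 88 at 6 h and 1 at 18 h.

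Some immediate early genes fell in the vehicle arrays from 1 to 18 h. IER3 fell by 1.66 ± 0.29, RNA45SN5, a ribosomal RNA gene, by 1.39, EGR1 by 1.24 ± 0.19, the histone gene H2AC6 by 1.17 and NR4A1 by 1.09 ± 0.33 (0.11 and -1.29 for its other probe sets). MFAP5, a microfibril protein, rose by 1.87 ± 0.56 (3.66-fold), CAPN6 by 1.54 ± 0.45 (2.91-fold), MXD3, a MYC antagonist, by 0.90 ± 0.13, TAF1A by 0.86 and KLHL28 by 0.86. Adjusted p was 0.000329 for IER3, 0.0453 for MFAP5 and 0.0459 for NR4A1. Limma called 648 genes, 274 higher and 374 lower, 2 and 8 of them at least 2-fold; 2286 had an unadjusted p under 0.05, and the block gave 1297 and 1474. Without vehicle replicate 4 at 18 h the count was 400, and MFAP5, CAPN6 and NR4A1 were not called in all 8 leave-1-out fits. Of 20 immediate early genes 6 fell, IER2 (-1.06), KLF2 (-0.92) and MYC (-0.77) included (adjusted p = 6.74e-09; 6 adjusted over the list alone, 13 with the block). Of 22 G1/S genes 6 fell, among them MCM5 (-0.63), E2F1 (-0.59), CDC6 (-0.44) and MCM3 (-0.41), which act in DNA replication (adjusted p = 6.96e-09, adjusted p = 0.519 with an estimated correlation; 14 adjusted over the list alone, 15 with the block). Of 23 G2/M genes 3 rose, CDK1 (0.43), BUB1B (0.33) and NUSAP1 (0.20), with adjusted p = 7.25e-05 (adjusted p = 0.555 with an estimated correlation; 8 adjusted over the list alone, 9 with the block). Of 17 cAMP-CREB targets NR4A1, CITED2 and DUSP1 fell (adjusted p = 0.00095, adjusted p = 0.555 with an estimated correlation; 9 with the block). PDE4A fell by 0.36, TSLP, an epithelial cytokine, rose by 0.56, and of the cell cycle inhibitors CDKN2B (0.59) and CDKN2D (0.55) rose and GADD45B (-0.40) fell. VLDLR (0.64) and DNAJB9 (0.31) rose and DDIT4 (-0.72) and PPP1R15A (-0.61) fell among stress response genes. Cholesterol synthesis genes had 0 called, 3 risen with the block, and adjusted p = 0.0101 (adjusted p = 0.555 with an estimated correlation). TXNRD1 (-0.28) was the 1 NRF2 target that fell (2 adjusted over the list alone, 6 with the block; adjusted p = 0.142, block 0.0208). Of glucocorticoid-inducible genes 2 fell, 7 with the block (adjusted p = 0.0863, block 0.014), and interferon-stimulated genes had adjusted p = 0.142, block 0.0303.

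Keratin and S100 genes of airway basal and squamous cells differed by replicate number. KRT14 had signals of 186900 to 441000 in the 12 replicate 3 arrays and of 13.3 to 31.9 in the other 36, which lay below the filter level of 75.42, so no fold is given. The highest signal of any probe set in those 36 arrays was 18549.7, so values above it in replicate 3 lie beyond the range the other arrays reach. S100A9 (60760 to 1389000) and KRT5 (29510 to 36310) lay wholly and ADIRF (14530 to 24760) partly beyond that range, and no sizes are given for them. SFN was higher there by 2.65 and LAMB3 by 1.99, while ITGA6 differed by 0.08. ALPP, a placental phosphatase, had signals of 0.9367 to 149.8 there, with a median below the filter level, and 274 to 1650 in the others. BCHE, butyrylcholinesterase, had 152.4 to 252.6 there and 208 to 5530 in the others, so its low level was not particular to replicate 3. In replicate 3, 173 genes lay at least 1 log2 unit above each other replicate number, against 4, 0 and 0 for replicates 1, 2 and 4. The list median was 1.64 for basal and squamous markers, -0.44 for interferon-stimulated genes, 0.46 for glucocorticoid-inducible genes, 0.26 for cAMP-CREB targets and 0.05 for reference genes. Within replicate 3, S100A9 values lay higher with both treatments than with vehicle at each time, but all lay beyond that range, and with 1 replicate 3 array per group this was not tested. From replicates 1, 2 and 4 alone, 311, 360, 415 and 2 genes were called with Ind/GSK and 50, 356, 222 and 1 with GS-5759, at 1, 2, 6 and 18 h.

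**Figure D3:**
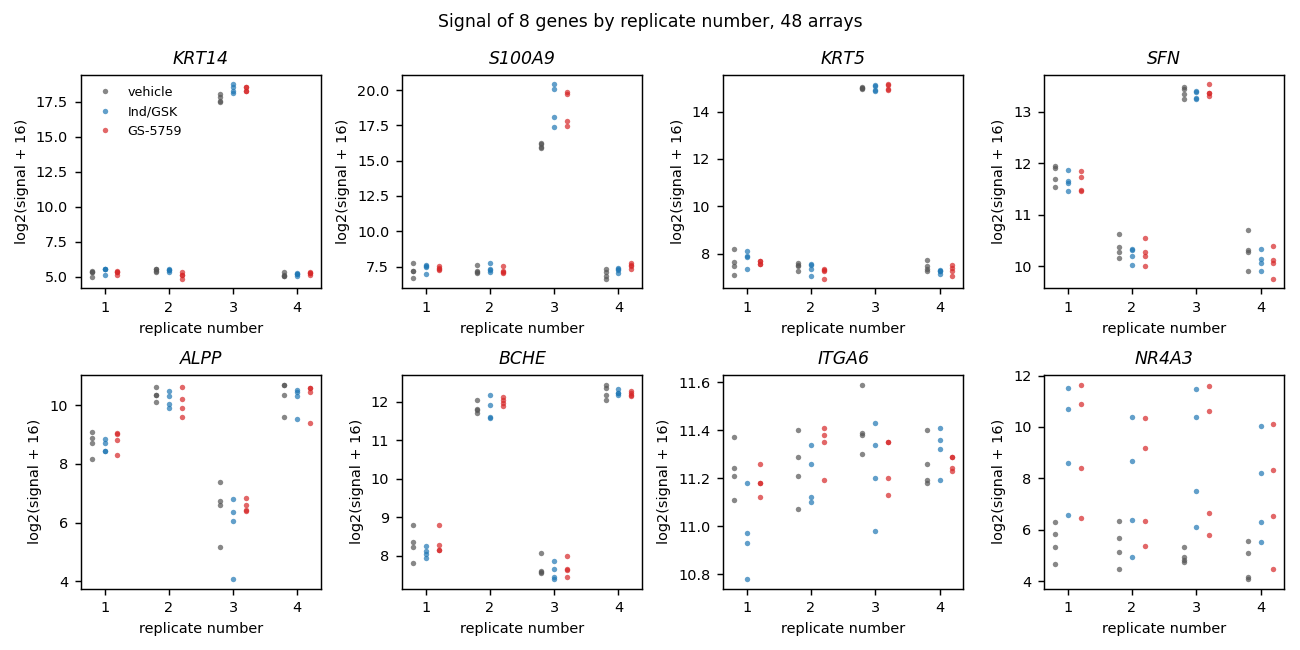
Signal of KRT14, S100A9, KRT5, SFN, ALPP, BCHE, ITGA6 and NR4A3 as log2(signal + 16) by replicate number. Points are the 48 arrays, coloured by treatment (grey vehicle, blue Ind/GSK, red GS-5759).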

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

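The tests of scaling, of falls shared by both treatments and of the few calls at 18 h were written before their results were seen; those of replicate 3, of RNA degradation and all splits were written after the result was seen. No biological explanation given by the design was tested for the replicate 3 pattern, as no group of the design separates that number.

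Basal and squamous genes such as KRT14, KRT5 and S100A9 were far higher in the 12 replicate 3 arrays, and in all 12 groups the replicate 3 array lay apart from the other 3 in the mean of that list (ratios 0.846 to 0.968). A minor share of other cells would raise genes without lowering many, yet 95 genes, ALPP among them, lay at least 1 log2 unit below each other replicate number, which speaks against it. Misread probe sets are unlikely, since 93.9% of the other probe sets of shifted genes moved the same way. A culture of another type or state as a whole remains possible, with a marker list median of 1.64, but this could not be separated from other causes here. No batch information was given.

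The falls called with Ind/GSK at 1 h, such as those of ZNF57 and SERTAD3, were small, and the Ind/GSK arrays had a lower bright end. After 75th percentile centring 15 of the 199 fallen genes stayed called as fallen, and 20 after quantile normalization. Their median change went from -0.29 (SD 0.10) to -0.17 (SD 0.10) and -0.19 (SD 0.11), while that of all genes went from -0.097 to 0.024 and -0.006. The calls ended because all genes moved by about as much. The 14 probe sets of added hybridization controls averaged log2 10.337 to 10.53 in the Ind/GSK arrays at 1 h. They averaged 10.636 to 10.721 with vehicle and 10.617 to 10.737 with GS-5759. These arrays were thus lower in controls that the cells do not make. Such an offset may make up part of these falls, and its share was not measured. RNA degradation would raise the GAPDH 3' signal over the 5' signal, and this difference was 0.046 higher than with vehicle (SD 0.031, 16 pairs). It lay below the bound of 0.15, set after the result was seen. The ACTB difference went the other way with Ind/GSK (-0.062, SD 0.089, 16 pairs), which degradation would not give. The pairs repeat replicate numbers over times, so no p-value is given and degradation stays open. Some falls may be shared by both treatments, as these genes had a median 0.10 lower than all genes with GS-5759 at 2 h (-0.1 in difference), 84.9% of them below 0 against 53.9% of all genes.

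Few genes were called at 18 h, when CSGALNACT1 and CRISPLD2 had returned toward vehicle. Residual SD at 18 h was 1.09 times that at 2 h, but the calls share 1 spread, so spread stays open as a cause. Rising vehicle levels are unlikely, making up 0.816% of the loss of response from 6 to 18 h in 116 genes risen with both treatments. A return of treated levels is the likely course, making up 99.2% of that loss, while the mean response went from 0.79 to 0.14 and 92 of the 116 genes stayed above 0.

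Whether chance could give the called counts was tested by regrouping the arrays without regard to replicate number. The replicate numbers pair the arrays, and the 8 splits of 2 groups that part every pair are too few for a share under 0.05, so what follows holds for splits that ignore the pairing. No other split gave as many genes as the real grouping with Ind/GSK at 2 h (503, 1 of 35 splits, the real one, and highest other 57). The same was seen at 6 h (537, 1 of 35, highest other 3). The same holds for GS-5759 at 1 h (39; 1 of 35; highest other 1), 2 h (350; 1 of 35; highest other 1) and 6 h (228; 1 of 35; highest other 2), and for vehicle at 18 h against 1 h (648; 1 of 35; highest other 1). For the difference between treatments over 4 times 2 of 100 drawn splits, the real one included, gave as many as 13 (highest other 578). Leaving out 1 replicate number gave from 0 to 4 genes there. For the responses at 6 h against 2 h 2 of 100 gave as many as the real 82 (highest other 131). All these splits mix replicate numbers, while the real grouping holds each number once in every group, so their shares alone do not exclude chance.

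Other splits did reach the real count with Ind/GSK at 1 h, where 2 of 35, the real one included, gave as many as 264 (highest other 560). At 18 h 2 of 35 gave as many as the real 7 (highest other 424). Chance cannot be excluded at these times. It cannot be excluded for the responses at 2 h against 1 h, where 12 of 100 gave as many as the real 19 (highest other 218), or at 18 h against 6 h, where 7 of 100 gave as many as the real 52 (highest other 1531). Where 0 genes were called, every split reaches that count and the test says nothing: 35 of 35 for GS-5759 at 18 h (highest other 237) and for the treatments against each other at 1, 2, 6 and 18 h (highest other 1, 47, 169 and 438). Splits that call several times the real count point to a structure of the samples; the highest at 18 h set replicates 1 and 3 against 2 and 4. Among the 8 splits that part every same-numbered pair, the real grouping gave the most with the block where it called any. With Ind/GSK it gave 2608 against 29 at 1 h and 271 against 3 at 18 h, but 8 are too few for a share under 0.05. In 100 draws that keep replicate numbers together, 1, 10, 1 and 13 gave as many for the difference between treatments and the changes at 2, 6 and 18 h.

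In sets of 4 arrays, 80 of 1308 sets of the 109 named genes had 1 array apart from the others by Dixon's ratio, where chance flags about 1 in 20 groups, here 65. Replicates 1, 2, 3 and 4 were the array apart in 16, 6, 48 and 10 of them. Means of the other gene lists had 1 array apart in 10 of 276 sets, where chance gives 14; replicate 3 was apart in 8 of the 10, with YAP and SRF target genes in 3 groups. A difference between groups marked the 13 genes called between the treatments over 4 times, PALMD leading. It also marked the 19, 82 and 52 genes whose response changed at 2, 6 and 18 h, with CRISPLD2 and CSGALNACT1 leading. Signal in data the comparisons do not use was seen among 5653 probe sets with no symbol or several: 82, 51 and 38 were called with Ind/GSK at 1, 2 and 6 h, and 12, 65, 34 and 1 with GS-5759 at 1, 2, 6 and 18 h.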

How the results depend on the processing

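Fits without replicate 3 and fits joining a scaling with the replicate block were chosen after the data were seen; the other alternatives were chosen before. Unless said otherwise, counts are genes called with Ind/GSK at 1, 2, 6 and 18 h, then with GS-5759 at the same times, and the cause of a shift was not tested. A count is said to have moved where it differed by more than 1.5 times.

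With the replicate number as a block the counts were 2608, 1708, 2567 and 271, and 195, 1344, 1526 and 21, against 264, 503, 537 and 7, and 39, 350, 228 and 0. The difference between treatments over 4 times went from 13 to 2060, the responses at 2, 6 and 18 h from 19, 82 and 52 to 343, 704 and 832, and vehicle over time from 648 to 2771. By construction the block takes differences between replicate numbers out of the spread. Of the named genes refitted the block changed only the calls of PDE4B and PDE4D given in the report, and it changed no other named call. In 408 list tests it made 4 weaker and 23 stronger. With the replicate number as a random effect, another use of that pairing, the counts were 2144, 1502, 2076 and 99, and 150, 1121, 1159 and 2, then 1442, 249, 490 and 561, and 2278 for vehicle.

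Joined with the block, 75th percentile centring gave 627, 1779, 2417 and 417, and 231, 1977, 2300 and 36, then 3 for the treatments against each other at 1 h, 274 over 4 times, 357, 1097 and 1457 for the responses, and 3287 for vehicle. Quantile normalization with the block gave 560, 1741, 2527 and 469, and 237, 1783, 2098 and 37, then 126, 335, 1159 and 1402, and 3457. From replicates 1, 2 and 4 with the block the counts were 2242, 854, 1570 and 19, and 158, 870, 817 and 5, then 25, 314, 394 and 428, and 2171.

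Scaling alone moved fewer counts. After 75th percentile centring GS-5759 at 18 h had 1 gene, the treatments differed in 2 at 1 h and in 84 over 4 times, and the response at 18 h against 6 h had 150. Quantile normalization gave 103 with Ind/GSK at 1 h, 1 with GS-5759 at 18 h, 35 over 4 times, and 131 and 127 for the responses at 6 and 18 h. Named genes kept their call in 246 of 259 cases after 75th percentile centring, with 12 weaker and 1 stronger, and in 244 after quantile normalization, with 15 weaker. Of 408 list tests 13 were weaker and 7 stronger after 75th percentile centring. With log2(value + 1) no count moved, and 4 of 259 named calls were lost, among them those of NR4A3 and PRDM1 at 6 h against 2 h. An estimated correlation between genes made 49 of 408 list tests weaker, and 359 stayed the same.

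From only the arrays of the groups named, the spread rests on fewer arrays, and the counts were 8, 70, 15 and 0, and 18, 104 and 9, then 39 and 21 for the responses at 6 and 18 h and 95 for vehicle. Called genes of at least 2-fold numbered 18, 59, 32 and 1, and 19, 67 and 25, then 0 over 4 times, 5, 16 and 9 for the responses and 10 for vehicle, as such a size must lower them. From replicates 1, 2 and 4 alone Ind/GSK at 18 h had 2, GS-5759 at 18 h 1, the difference over 4 times 2, and the responses at 2 and 18 h 58 and 81. Of the named calls 210 of 259 stayed the same there, with 47 weaker and 2 stronger.

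Every probe set tested on its own gave 492 with Ind/GSK at 1 h, 1 between the treatments at 6 h, 127 over 4 times, 52 for the response at 2 h and 1013 for vehicle. No filter gave 7 over 4 times and a correlation of the responses of 0.828 at 6 h. A 60th percentile filter gave 31 for the response at 2 h, and trend and robust fitting 20 over 4 times. Over only the genes called in either treatment the correlations were 0.983, 0.985 and 0.987 at 1, 6 and 18 h, as such genes have the larger changes. Signal over background limits the dim genes: those under the filter were not tested, and a fold change near it is drawn toward 0 by the added 16.

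Another probe set of a named gene was the same in 182 of 281 cases, weaker in 78 and opposite in sign in 21. The opposite values are listed here; NR4A1, MVK and YWHAZ also had other probe sets with the same sign, given in the report. For CRISPLD2 it gave -0.15 and -0.04 with Ind/GSK at 2 and 6 h, -0.17 and -0.21 with GS-5759, and -0.09 and 0.10 for the responses at 2 and 18 h. For NR4A1 1 of 2 gave -0.03 with GS-5759 at 1 h, -0.11 with Ind/GSK at 2 h, -0.17 with GS-5759 at 2 h and 0.11 for vehicle over time. CSGALNACT1 had -0.15 with GS-5759 at 6 h and 0.07 for the response at 18 h. CXCL2 had -0.06 and -0.05 at 2 h with Ind/GSK and GS-5759, 1 of 3 for MVK 0.01 with Ind/GSK at 6 h and -0.07 for the response at 18 h. 1 of 4 for YWHAZ had 0.01 with Ind/GSK at 2 h and CCNB2 0.28 at 6 h. For the difference over 4 times ARAP2 had -0.08 and -0.07, and LINC01366 0.03. Among the weaker ones, 1 probe set gave 0.01 for PLAUR, -0.02 for CDC25C and -0.18 for AURKA with Ind/GSK at 2 h, -0.10 for LOC401261 at 1 h and -0.08 for CLIC5 at 18 h.

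Leaving out 1 array or replicate number moved 49 of 168 counts and correlations. Without 1 array, counts ran from 74 to 433, 268 to 477, 240 to 581 and 1 to 12 with Ind/GSK. They ran from 31 to 39, 238 to 312, 97 to 202 and 0 to 3 with GS-5759, and from 400 to 603 for vehicle. Without 1 replicate number the difference over 4 times gave 0 to 4, the responses 5 to 80, 7 to 78 and 7 to 81. Correlations of the responses ranged from 0.574 to 0.88, 0.779 to 0.945, 0.708 to 0.912 and 0.533 to 0.917; all lowest values came without a treated replicate 3 array and all highest without the vehicle replicate 3 array. Of 1932 calls of named genes 1581 stayed the same and the others were weaker.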

Other observations

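Genes called and changed at least 2-fold (18, 59 and 32 with Ind/GSK and 19, 67 and 25 with GS-5759 at 1, 2 and 6 h) had slopes that varied by replicate number. Slopes of each replicate's change on the mean change, for replicates 1, 2, 3 and 4, were 1.13, 0.77, 1.33 and 0.79 with Ind/GSK at 1 h, 1.13, 0.79, 1.21 and 0.85 at 2 h, and 1.14, 0.78, 1.20 and 0.83 at 6 h. With GS-5759 they were 1.18, 0.88, 1.22 and 0.73, then 1.13, 0.83, 1.17 and 0.85, and 1.15, 0.87, 0.97 and 0.95.

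Further genes beyond the fixed lists differed in replicate 3. S100A8, a calcium-binding protein, was higher there by 5.56 (signals of 856 to 8744), LMO2, a transcription cofactor, by 5.53, SULT1E1, an estrogen sulfotransferase, by 5.08, S100A2 by 4.74 and the protease inhibitor SLPI by 4.54. S100A8, LMO2, SULT1E1 and SERPINB5 had median signals of 36.1, 30.7, 46 and 43 in the other arrays, below the filter level of 75.42, so their sizes depend on the added 16. FGFBP1 was higher by 4.22, SERPINB5 by 4.07 and the water channel AQP3 by 3.85. MX2, an interferon-induced gene, was lower by 2.09 and L1CAM, an adhesion protein, by 1.96. In all, 341 genes were at least 1 log2 unit above and 203 below the mean of the other numbers. So far below each other number lay 95, against 0 for replicates 1, 2 and 4.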
